A study of Homo sapiens with 18 samples.

How the data were processed

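The samples were 18 RNA sequencing libraries from MCF7, an established human breast cancer cell line that carries the estrogen receptor. They came from tamoxifen-sensitive cells with a non-silencing control construct, tamoxifen-resistant cells with the same kind of control, and tamoxifen-resistant cells in which the mRNA for eIF4E, the cap-binding subunit of the translation initiation complex, was silenced. In each of these 3 conditions polysome profiling, the separation of mRNAs by the number of ribosomes they carry, gave 3 kinds of library with 2 replicates each: total mRNA, light polysomes (2 to 3 ribosomes per mRNA) and heavy polysomes (more than 4 ribosomes). The resistant cells received 1 µM 4-hydroxytamoxifen, the active form of tamoxifen, every 72 h, and the medium held 5% serum. The libraries were made from polyadenylated RNA, so mRNAs with short or absent tails, such as most histone mRNAs, are measured incompletely.

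The deposited values are counts of reads per gene symbol, not normalised by the authors. Each library lists 23368 genes, followed by 5 HTSeq summary lines that were set aside before any test. Per the submitters' processing notes, which give no role or order, Trimmomatic 0.33, TopHat2 2.0.9, Bowtie 1.0.0.0, HTSeq 0.6.1p1 and limma were used, with genome build hg19. The annotation release, the strand setting and the handling of duplicate reads are not given in the sources used here. Genes that overlap, lie antisense to one another or share sequence with paralogs or pseudogenes (ribosomal protein genes, histone genes, the HOXB cluster and its antisense transcript, IPW) are therefore uncertain in their exact level. Gene counts per library ranged from 35.6 to 65.3 M. Reads outside genes made up 5.81 to 14.9% of all reads, ambiguous reads 1.78 to 2.87% and reads with more than 1 alignment 8.09 to 14.9%. The 10 most abundant genes of a library held 3.65 to 5.39% of its gene counts. At this depth counting error is small for all but rare transcripts, and the spread between replicate libraries sets the precision: the chi-square of replicate counts over its degrees of freedom was 32.1 to 123, and the standard deviation of the log2 difference between replicates ran from 0.409 in total mRNA of silenced cells to 0.718 in total mRNA of sensitive cells.

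All 18 libraries entered a single model with 9 groups (condition by fraction), fitted by robust quasi-likelihood in edgeR 4.0.16 under R 4.3.3. Low-count genes were removed with filterByExpr, which left 15845 of the 20402 genes with a count, and library sizes were scaled by TMM. The model had 9 residual degrees of freedom, a common biological coefficient of variation of 0.196 and a median of 4.65 prior degrees of freedom. Each of 13 comparisons was a contrast of this model, 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. Resistance was tested as resistant minus sensitive cells, both with the control construct, in total, light and heavy mRNA. The effect of silencing was tested as silenced minus control resistant cells in the same 3 kinds of library. Translational efficiency was the interaction of a condition contrast with heavy against total mRNA, and ribosome number was the interaction with heavy against light mRNA. Silenced resistant cells were also set against sensitive cells in heavy mRNA, and heavy mRNA against total and light mRNA as the mean of the 3 conditions. Levels are given as CPM (counts scaled to a common effective library size), mean ± SD of 2 libraries, and folds as the model's log2 values with their standard errors (SE). The p-values measure only the spread between these samples, which come from 6 cultures of 1 cell line. Comparisons, tests, gene lists, the rule for named genes and the alternatives first listed below were fixed before the data were examined.

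Whether the replicate numbers join the fractions of a culture was checked on deviations from group means. Within a condition, fractions with the same number correlated at 0.330 to 0.680 across genes in 9 of 9 pairs. Across conditions the correlations were -0.120 to 0.250, and 14 of 27 exceeded 0.1. Silenced and sensitive cells correlated at 0.145 to 0.250 in 9 of 9 pairs and resistant and silenced cells at 0.124 to 0.236 in the 3 pairs of the same fraction, but at 0.0313 to 0.109 across fractions, and resistant and sensitive cells at -0.120 to -0.0318. Since not every pair exceeded 0.1, the numbers were read as 6 cultures, paired within a condition only, and a link between some cultures of the same number stays open. For the interactions and fraction contrasts, a model with each culture as a block was added after the data had been seen. It had 6 residual degrees of freedom and a coefficient of variation of 0.0889. The main model treats the fractions of a culture as independent libraries. Its 9 residual degrees of freedom therefore overstate the replication of the condition contrasts, which rest on 2 cultures per condition.

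Named genes followed a rule: EIF4E, the silenced gene, then ESR1, PGR, RUNX2, MKNK1, MKNK2, MTOR, EIF4EBP1, CCND1 and MYC. To these were added, in total and heavy mRNA, the 6 largest rises and the 6 largest falls that passed the test, reached 5 CPM in the higher group and had both replicates of one group above both of the other. The interactions and fraction contrasts took the 4 largest of each direction, each gene list up to 4 members with the smallest p, and a contrast in which no gene passed its 5 smallest p. Genes named outside this rule are said to be chosen after their values were seen. For a group with no count, a fold is a lower bound against a floor of 3 counts over the group. For a group with 1 to 3 counts it is a ratio with its 95% counting interval. These intervals and floors cover counting error only.

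The tested lists were ribosomal proteins, other mRNAs with a 5' terminal oligopyrimidine tract (TOP), eIF4F subunits and regulators, the mTOR pathway, classic eIF4E-sensitive mRNAs, estrogen-induced genes, luminal lineage genes, basal and mesenchymal genes, RUNX2 and bone-related targets, growth factor receptors, interferon-stimulated genes, NF-kB and inflammatory genes, cholesterol synthesis, nuclear-encoded oxidative phosphorylation, DNA replication, mitosis, the unfolded protein and integrated stress response, aminoacyl-tRNA synthetases, NRF2 targets, hypoxia and glycolysis, p53 targets, apoptosis regulators, proteasome subunits, immediate early genes, nuclear long noncoding RNAs, snoRNA host noncoding RNAs, replication-dependent histones, and leukocyte and endothelial markers. Each of these 28 lists was tested against all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry served as alternatives. Lists share members: 16 of the classic eIF4E-sensitive mRNAs, 9 apoptosis regulators and 8 estrogen-induced genes are also in another list. Mitochondrially encoded mRNAs were not analysed here, since none of their symbols matched, and fibroblast markers had fewer than the minimum of 5 tested members.

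The alternatives planned were RLE size factors, no low-count filter, a filter of 1 CPM in 6 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, a model of the contrast's own libraries, and each library left out. A model left with a single library in a group assumes that this library varies like those of the other groups. Added after the data had been seen were the culture block, the culture block with each culture left out, all 3 fractions of each culture left out, and the list tests under both. Figures were drawn with matplotlib 3.10.9.

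The procedure was tested on simulated data with 15845 genes and known folds. For the effect of silencing in heavy mRNA it recovered 1.49% of 1.5-fold, 41.8% of 2-fold and 86.4% of 4-fold changes, with 13 false calls. For resistance in heavy mRNA the shares were 0%, 34.3% and 75.8%, with 8 false calls. For translational efficiency after silencing they were 0%, 2.99% and 66.7% with 0 false calls, and 17.9%, 70.1% and 89.4% with 6 false calls under the culture block. For heavy against light mRNA after silencing they were 0%, 4.48% and 65.2% with 0 false calls, and 22.4%, 68.7% and 89.4% with 7 false calls under the culture block. In heavy mRNA the genes recovered at these folds were 1, 28 and 57 for silencing and 0, 23 and 50 for resistance. Beside them, the 13 and 8 false calls were a larger share of all calls than the threshold of 0.05, in 1 simulation each. With 1 list changed in the simulated silencing of heavy mRNA, the list test called it and 1 other list. The simulated genes varied independently of one another, so this did not test the preset correlation.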

Results

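The data are read counts per gene in 18 libraries of MCF7 breast cancer cells. There were 3 conditions: tamoxifen-sensitive cells with a non-silencing construct (sensitive), tamoxifen-resistant cells with a non-silencing construct (resistant) and tamoxifen-resistant cells with EIF4E silenced (silenced). Each condition was measured in total mRNA, light polysomes and heavy polysomes, with 2 libraries in each of the 9 groups. The counts assigned to genes ranged from 35.6 to 65.3 M per library. In a principal component analysis the components held 36.8%, 29.1%, 9.39% and 5.33% of the variance. The leading one parted sensitive from resistant cells, the next parted the fractions within each condition, and the third parted the replicates of the sensitive cells.

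EIF4E encodes the cap-binding protein that recruits ribosomes to mRNA and was the silenced gene. Its mRNA stood at 105 and 105 CPM in total mRNA of sensitive cells, 170 and 125 CPM in resistant cells and 74.0 and 77.4 CPM in silenced cells. In light polysomes the libraries held 142 and 190 CPM in sensitive, 360 and 272 CPM in resistant and 123 and 121 CPM in silenced cells. In heavy polysomes they held 37.5 and 49.5 CPM in sensitive, 91.7 and 68.4 CPM in resistant and 57.8 and 47.3 CPM in silenced cells. Both silenced libraries of a fraction were below both resistant ones in each of the 3 fractions. With silencing EIF4E fell by 1.38 on the log2 scale in light polysomes (SE 0.22, edgeR adjusted p = 0.0274, n = 2 per group). The log2 folds were -0.96 (SE 0.22, adjusted p = 0.483) in total mRNA and -0.61 (SE 0.22, adjusted p = 0.497) in heavy polysomes, which did not pass. The light call was lost without resistant light library 1 (-1.16, adjusted p = 0.434) or 2 (-1.57, 0.0907) and without silenced light library 1 (-1.41, 0.0871) or 2 (-1.37, 0.157), over a range of 1.73e-06 to 0.518 across all alternatives. Between resistant and sensitive cells EIF4E rose by 0.88 (SE 0.22, adjusted p = 0.0172) in heavy and by 0.93 (SE 0.21, adjusted p = 0.0109) in light polysomes, with 0.49 (SE 0.21, adjusted p = 0.168) in total mRNA. These calls were lost without resistant library 1 (heavy 0.65, adjusted p = 0.142; light 0.71, 0.108) or sensitive library 1 (heavy 0.66, 0.140; light 0.73, 0.0924), in ranges of 0.00205 to 0.142 for heavy and 0.000472 to 0.108 for light polysomes.

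**Figure D1:**
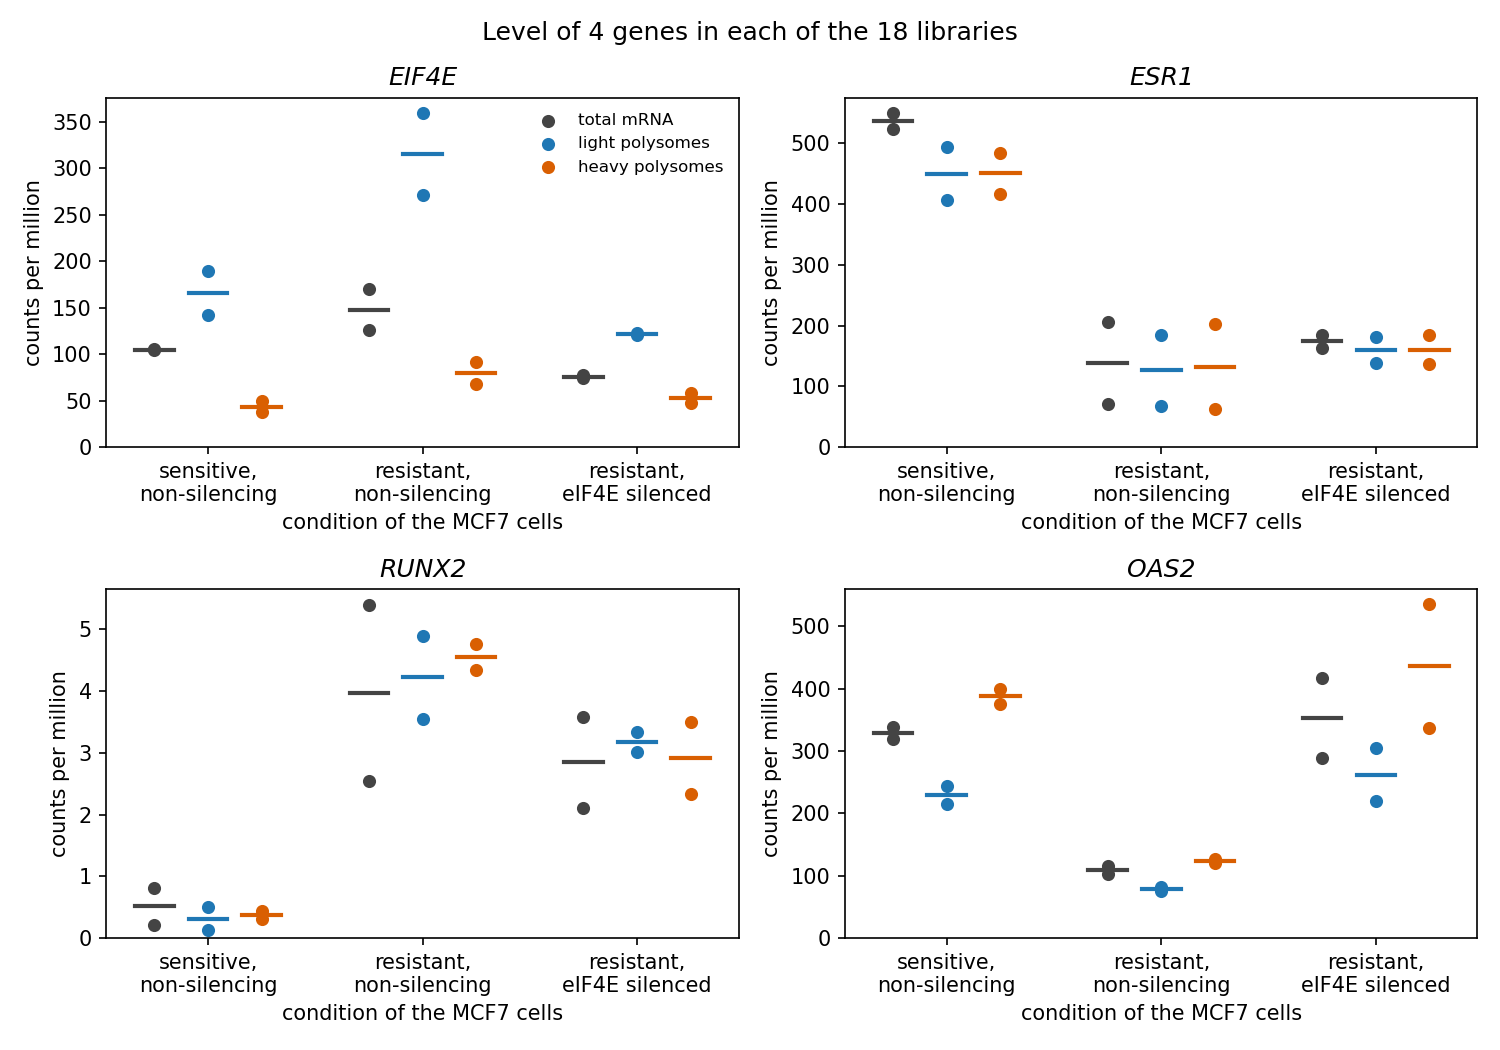
Level in CPM (vertical axis) of EIF4E, ESR1, RUNX2 and OAS2 in total, light and heavy mRNA (colours) of sensitive, resistant and silenced cells (horizontal axis), where points are libraries and bars are the mean of 2. EIF4E in light polysomes averages 166 in sensitive, 316 in resistant and 122 in silenced cells, and OAS2 in heavy polysomes 388, 123 and 437.

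Resistant against sensitive cells in total mRNA asks which transcripts differ with tamoxifen resistance. The resistant and silenced cells received 4-hydroxytamoxifen, and no dose is given for the sensitive cells. In every contrast with sensitive cells, resistance and the drug therefore cannot be told apart. GNAI1, an inhibitory G protein subunit, rose by 8.50 on the log2 scale (SE 0.41, adjusted p = 7.25e-08), from 0.0647 ± 0.0570 to 24.0 ± 0.323 CPM (SD, n = 2). PI15, a secreted peptidase inhibitor, rose by 7.47 (SE 0.35, adjusted p = 7.25e-08) to 101 ± 29.6 CPM, and the transcription factors HOXB3 and NR2F1 rose by 7.50 (SE 0.74) and 7.34 (SE 1.04). SLC5A8, a monocarboxylate transporter, rose by 6.29 (SE 0.81), and the imprinted noncoding RNA IPW had 736 counts against 1, a ratio of 620 with a counting interval of 111 to 24539. Of the falls, EPDR1, a lysosomal protein gene, had 0 counts against 416 and was at least 164-fold lower. FAM109B, an endosomal trafficking gene, fell by 5.85 (SE 0.42, adjusted p = 2.99e-06) to 0.202 ± 0.0306 CPM. GNPDA2, an amino sugar deaminase (-5.59, SE 0.56), CREB3L1, a transcription factor of the endoplasmic reticulum (-4.28, SE 0.66), and ABCC3, an organic anion exporter (-3.64, SE 0.34), fell as well. LRRN3, a leucine-rich repeat membrane protein gene, fell by 4.00 (SE 1.01, adjusted p = 0.0248), a call lost without resistant total library 1 (-3.40, 0.187) or 2 (-5.03, 0.0837) or sensitive total library 1 (-2.70, 0.159), in a range of 0.00234 to 0.187. The CREB3L1 call was lost without resistant culture 1 (-3.93, 0.0586), in a range of 4.59e-10 to 0.0586.

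ESR1, the estrogen receptor gene, was lower in resistant cells at -1.95 (SE 0.55, adjusted p = 0.0421) to 139 ± 95.6 CPM from 536 ± 19.3 CPM in total mRNA. In heavy polysomes ESR1 fell by 1.77 (SE 0.55, adjusted p = 0.0496). Its total call was lost without resistant library 1 (-1.38, 0.264) or sensitive library 1 (-1.91, 0.121) or 2 (-1.99, 0.0870), in a range of 0.000657 to 0.264. Its heavy call was lost without the same libraries of heavy polysomes (-1.16, 0.269; -1.91, 0.0925; -1.65, 0.134), in a range of 0.000697 to 0.269. RUNX2, a master regulator of bone formation, rose by 2.94 (SE 0.58, adjusted p = 0.00653) in total mRNA, from 0.517 ± 0.420 to 3.96 ± 2.01 CPM, and by 3.64 (SE 0.60, adjusted p = 0.00169) in heavy polysomes. The total call of RUNX2 was lost without resistant library 1 (2.30, 0.0688), in a range of 1.04e-05 to 0.125. The progesterone receptor gene PGR (0.48 in total, 0.61 in heavy), the eIF4E kinase genes MKNK1 (0.05, 0.20) and MKNK2 (-0.16, -0.19), the growth kinase gene MTOR (0.36, 0.11), its target EIF4EBP1 (0.65, 0.53), the cyclin gene CCND1 (0.35, 0.29) and the growth regulator MYC (-0.39, -0.46) did not pass in either.

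In total mRNA 745 genes rose and 768 fell, 1513 of 15845 tested, with a median absolute log2 fold of 1.09. At an unadjusted p under 0.05 there were 3933. The count was 566 without resistant total library 1, 573 without resistant total library 2 and 726 without sensitive total library 1.

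Among the gene lists in total mRNA, estrogen-induced genes were higher in resistant cells: 11 of 44 rose and 1 fell (12 and 2 adjusted over the list alone), with a median log2 fold of 0.59 (camera adjusted p = 4.69e-07) and adjusted p = 0.029 with an estimated correlation. ELOVL2, a fatty acid elongase, rose by 4.30 (SE 0.40) to 103 CPM, GREB1, an estrogen receptor cofactor, by 2.36 (SE 0.28) and CXCL12, a chemokine, by 2.23 (SE 0.27). Interferon-stimulated genes were lower: 13 of 45 fell and 1 rose (18 and 1 adjusted over the list alone), with a median of -0.57 (adjusted p = 1.49e-09), and adjusted p = 0.466 with an estimated correlation. The antiviral sensor DDX58 (-1.51, SE 0.21), the antiviral enzyme OAS2 (-1.59, SE 0.23) and RSAD2, which blocks viral replication (-2.49, SE 0.38), fell. Of the immediate early genes 11 of 26 fell and 1 rose (17 and 2 adjusted over the list alone; median -1.14, adjusted p = 1.16e-09, and adjusted p = 0.282 with an estimated correlation), among them the phosphatase gene DUSP5 (-1.06) and the stress-induced survival gene IER3 (-1.51). NF-kB and inflammatory genes were lower as well, with 4 of 18 falling (9 down and 1 up adjusted over the list alone; median -0.83, adjusted p = 0.000632, and adjusted p = 0.466 with an estimated correlation), such as TNFAIP2 (-3.99) and the NF-kB cofactor BCL3 (-1.24). Replication-dependent histones, measured incompletely in polyadenylated RNA, had 7 of 22 members down (8 adjusted over the list alone; median -0.85, adjusted p = 1.19e-06, and adjusted p = 0.466 with an estimated correlation). Without resistant culture 1 or 2 the members that fell were 5 and 2 for interferon-stimulated genes, 7 and 4 for immediate early genes and 2 and 1 for histones, and NF-kB genes were 2 without the latter. The 5 lists of this paragraph kept their call and direction without any culture. Of the genes, RSAD2 was lost without resistant culture 2 (-2.34, adjusted p = 0.0567, in a range of 1.79e-09 to 0.0567) and BCL3 without resistant culture 1 (-1.07, 0.0864, in a range of 6.35e-07 to 0.0864).

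Several more lists were called slightly higher in total mRNA of resistant cells, none of them with an estimated correlation. DNA replication genes had 6 of 44 up (10 adjusted over the list alone; median 0.30, adjusted p = 5.15e-06, and adjusted p = 0.269 with an estimated correlation), with GINS4 of the replicative helicase at 0.94 (SE 0.17). Aminoacyl-tRNA synthetases had 5 of 20 up (8 alone; median 0.32, adjusted p = 0.00128, and adjusted p = 0.466 with an estimated correlation). Oxidative phosphorylation had 5 of 74 up (4 alone; median 0.27, adjusted p = 0.000319), including the ATP synthase subunit ATP5G1 at 0.96 (SE 0.17), proteasome subunits 3 of 31 (7 alone; median 0.26, adjusted p = 0.00125) and other TOP mRNAs 2 of 27 (2 alone; median 0.29, adjusted p = 0.00215), including IMPDH2, a guanine nucleotide synthesis enzyme, at 0.91 (SE 0.14); each had adjusted p = 0.778 with an estimated correlation. No ribosomal protein gene of 77 passed, and their list was called (median 0.32, adjusted p = 0.00125, and adjusted p = 0.799 with an estimated correlation). Without sensitive culture 2 these last 4 lists lost their calls, with adjusted p = 0.232 for oxidative phosphorylation, 0.309 for the proteasome, 0.181 for other TOP mRNAs and 0.412 for ribosomal proteins. The ribosomal protein call was also lost without resistant culture 2 (adjusted p = 0.0694). With resistant culture 1 or 2 left out the members that rose were 1 and 1 for DNA replication, 0 and 1 for synthetases and 1 and 0 for oxidative phosphorylation. ATP5G1 was lost without resistant culture 2 (0.90, adjusted p = 0.0613, in a range of 1.12e-05 to 0.0613).

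The other lists were not called in total mRNA. In receptors, IGF1R, the insulin-like growth factor receptor, rose by 1.46 (SE 0.19) and the epidermal growth factor receptor EGFR fell by 2.08 (SE 0.33), while the list of 17 had a median of -0.32 (adjusted p = 0.666). Cholesterol synthesis had a median of 0.21 (adjusted p = 0.245), with squalene synthase FDFT1 up by 1.89 (SE 0.31). The p53 targets had a median of 0.13 (adjusted p = 0.350), with the RNA-binding growth inhibitor ZMAT3 up by 1.35 (SE 0.19). Apoptosis regulators had a median of -0.01, a mean of 0.05 and a test direction of down (adjusted p = 0.902), with the pro-apoptotic BMF down by 1.38 (SE 0.22). EGFR was lost without resistant culture 2 (-2.04, 0.0520, in a range of 0.000121 to 0.0525) and BMF without resistant culture 1 (-1.37, 0.0525, in a range of 5.96e-08 to 0.0525). Medians and adjusted p were 0.16 and 0.666 for eIF4F subunits and regulators, 0.09 and 0.789 for the mTOR pathway, 0.10 and 0.650 for classic eIF4E-sensitive mRNAs, -0.30 and 0.350 for luminal genes, -0.35 and 0.350 for basal and mesenchymal genes and 0.02 and 0.878 for RUNX2 and bone-related targets. They were 0.14 and 0.125 for mitosis, -0.01 and 0.156 for NRF2 targets, 0.19 and 0.270 for hypoxia and glycolysis and 0.21 and 0.156 for snoRNA hosts. The unfolded protein and stress response list had a median of 0.13 and a mean of 0.03 but a test direction of down (adjusted p = 0.970). Nuclear long noncoding RNAs (median -0.02, mean 0.22, test down, adjusted p = 0.902) and leukocyte and endothelial markers (median -0.08, mean 0.49, test down, adjusted p = 0.902) also differed in sign between measures.

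The same contrast in heavy polysomes asks which mRNAs differ where they carry many ribosomes. PI15 rose by 8.22 (SE 0.37, adjusted p = 5.96e-08) to 84.5 ± 6.79 CPM and GNAI1 by 8.11 (SE 0.38, adjusted p = 5.96e-08) to 26.5 ± 3.01 CPM. SLC5A8 rose by 7.68 (SE 0.90), the homeobox genes HOXB2 and HOXB3 by 7.12 (SE 0.86) and 7.05 (SE 0.71), and IPW had 436 counts against 1, a ratio of 490 with an interval of 87.4 to 19382. EPDR1 had 1 count against 614, a ratio of 547 in favour of sensitive cells with an interval of 97.8 to 21631. FAM109B (-6.06, SE 0.42), GNPDA2 (-5.14, SE 0.55), CREB3L1 (-3.87, SE 0.65), TNFAIP2 (-3.80, SE 0.51) and the ubiquitin ligase gene CBLC (-3.79, SE 0.49) fell. The CREB3L1 call was lost without resistant culture 1 (-3.45, 0.0630), in a range of 1.64e-08 to 0.0630. In heavy polysomes 1080 genes rose and 1018 fell, with a median absolute log2 fold of 0.97. The 2098 calls were 1017 and 809 without resistant heavy library 1 or 2, and 1097 and 1162 without sensitive heavy library 1 or 2. Total and heavy mRNA shared 548 risen and 595 fallen genes, against 50.8 and 49.3 for independent sets, and their folds correlated at 0.862 across all genes. The 2 kinds of library were read as coming from the same cultures, so independent sets are not a measure of chance here and part of the overlap may come from the cultures.

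In heavy polysomes 11 of 44 estrogen-induced genes rose and 1 fell (13 and 1 adjusted over the list alone; median 0.58, adjusted p = 8.65e-07, and adjusted p = 0.0339 with an estimated correlation). PRSS23, a secreted serine protease, rose by 4.81 (SE 0.55) from 6.32 to 175 CPM, and the small heat shock protein gene HSPB8 by 1.93. Of 45 interferon-stimulated genes 14 fell (20 down and 1 up adjusted over the list alone; median -0.70, adjusted p = 3.23e-10, and adjusted p = 0.445 with an estimated correlation), including OAS2 (-1.65) and IRF9, a mediator of interferon signalling (-1.15). Of 26 immediate early genes 12 fell and 2 rose (18 and 2 adjusted over the list alone; median -1.22, adjusted p = 3.23e-10, and adjusted p = 0.338 with an estimated correlation), among them IER3 (-1.69, SE 0.19) and ZFP36, which speeds decay of inflammatory mRNAs (-1.92, SE 0.28). The NF-kB list (4 down, 1 up; 4 and 1 alone; median -0.71, adjusted p = 0.00210) and the histone list (6 down; 8 alone; median -1.08, adjusted p = 1.51e-06) were lower, and both had adjusted p = 0.445 with an estimated correlation. DNA replication was higher (7 up; 7 alone; median 0.25, adjusted p = 0.000758, and adjusted p = 0.445 with an estimated correlation). Without resistant culture 1 or 2 the estrogen-induced members that rose were 11 and 9, the interferon-stimulated members that fell 7 and 6, and the DNA replication members that rose 2 and 1. Immediate early genes that fell then numbered 15 and 5, and histones 2 and 1, while histones were 11 without sensitive culture 2 and NF-kB genes 2 without resistant culture 2.

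Ribosomal proteins (0 of 77 passing; median 0.31, adjusted p = 0.00210), oxidative phosphorylation (6 up; 4 alone; median 0.22, adjusted p = 0.00809) and proteasome subunits (2 up; 0 alone; median 0.28, adjusted p = 0.00210) were called up in heavy polysomes, each with adjusted p = 0.739 with an estimated correlation. Other TOP mRNAs (4 up; 7 alone; median 0.30, adjusted p = 0.00923) and mitosis (4 up; 4 alone; median 0.23, adjusted p = 0.0166) were called too, each with adjusted p = 0.738 with an estimated correlation. Without sensitive culture 2 adjusted p was 0.780 for ribosomal proteins (median -0.03), 0.701 for oxidative phosphorylation (median -0.01), 0.137 for the proteasome and 0.187 for other TOP mRNAs. Mitosis was lost without sensitive culture 1 (0.0602) or resistant culture 2 (0.0645), and oxidative phosphorylation without resistant culture 2 (0.0718). Without resistant culture 1 or 2 the members that rose were 1 and 1 for oxidative phosphorylation, 1 and 0 for other TOP mRNAs and 0 and 0 for mitosis. The anti-apoptotic BCL2, a member of the classic eIF4E-sensitive, luminal lineage and apoptosis lists, rose by 1.17 (SE 0.20). The classic eIF4E-sensitive list was not called (median 0.29, camera adjusted p = 0.172).

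Light polysomes asked the same of mRNAs with few ribosomes, where 947 genes rose and 1420 fell. With resistant light library 2 left out, falls no longer outnumbered rises. The antisense transcript HOXB-AS3 had 585 counts against 0 and was at least 187-fold higher, and EPDR1 had 0 against 528 and was at least 183-fold lower. HOXB3 rose by 8.08 (SE 0.74), PI15 by 6.95 (SE 0.34) and GNAI1 by 6.91 (SE 0.37), and FAM109B fell by 6.02 (SE 0.42); these genes of light polysomes were chosen after their values were seen. RUNX2 rose by 3.76 (SE 0.61, adjusted p = 0.00146). Interferon-stimulated genes (17 of 45 down; 21 alone; median -0.70, adjusted p = 4.93e-08, and adjusted p = 0.688 with an estimated correlation) were lower. Histones (12 of 22 down; 20 alone; median -1.26, adjusted p = 3.43e-07) and immediate early genes (13 of 26 down, 2 up; 20 and 2 alone; median -1.07, adjusted p = 4.93e-08) were lower too, each with adjusted p = 0.534 with an estimated correlation. Estrogen-induced genes had 12 of 44 up and 5 down (12 and 5 alone; median 0.34, adjusted p = 0.000471, and adjusted p = 0.241 with an estimated correlation). With resistant culture 1 or 2 left out there were 8 and 10 estrogen-induced rises, and falls of 6 and 4 interferon-stimulated genes, 11 and 4 immediate early genes and 2 and 1 histones. Ribosomal proteins (median 0.35, adjusted p = 3.65e-05) and oxidative phosphorylation (0.19, 0.00132) were higher, each with adjusted p = 0.786 with an estimated correlation, and both were lost without sensitive culture 2 (0.210 and 0.642). The 2367 calls were 1027 and 978 without resistant light library 1 or 2, and 1460 and 1561 without sensitive light library 1 or 2.

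**Figure D2:**
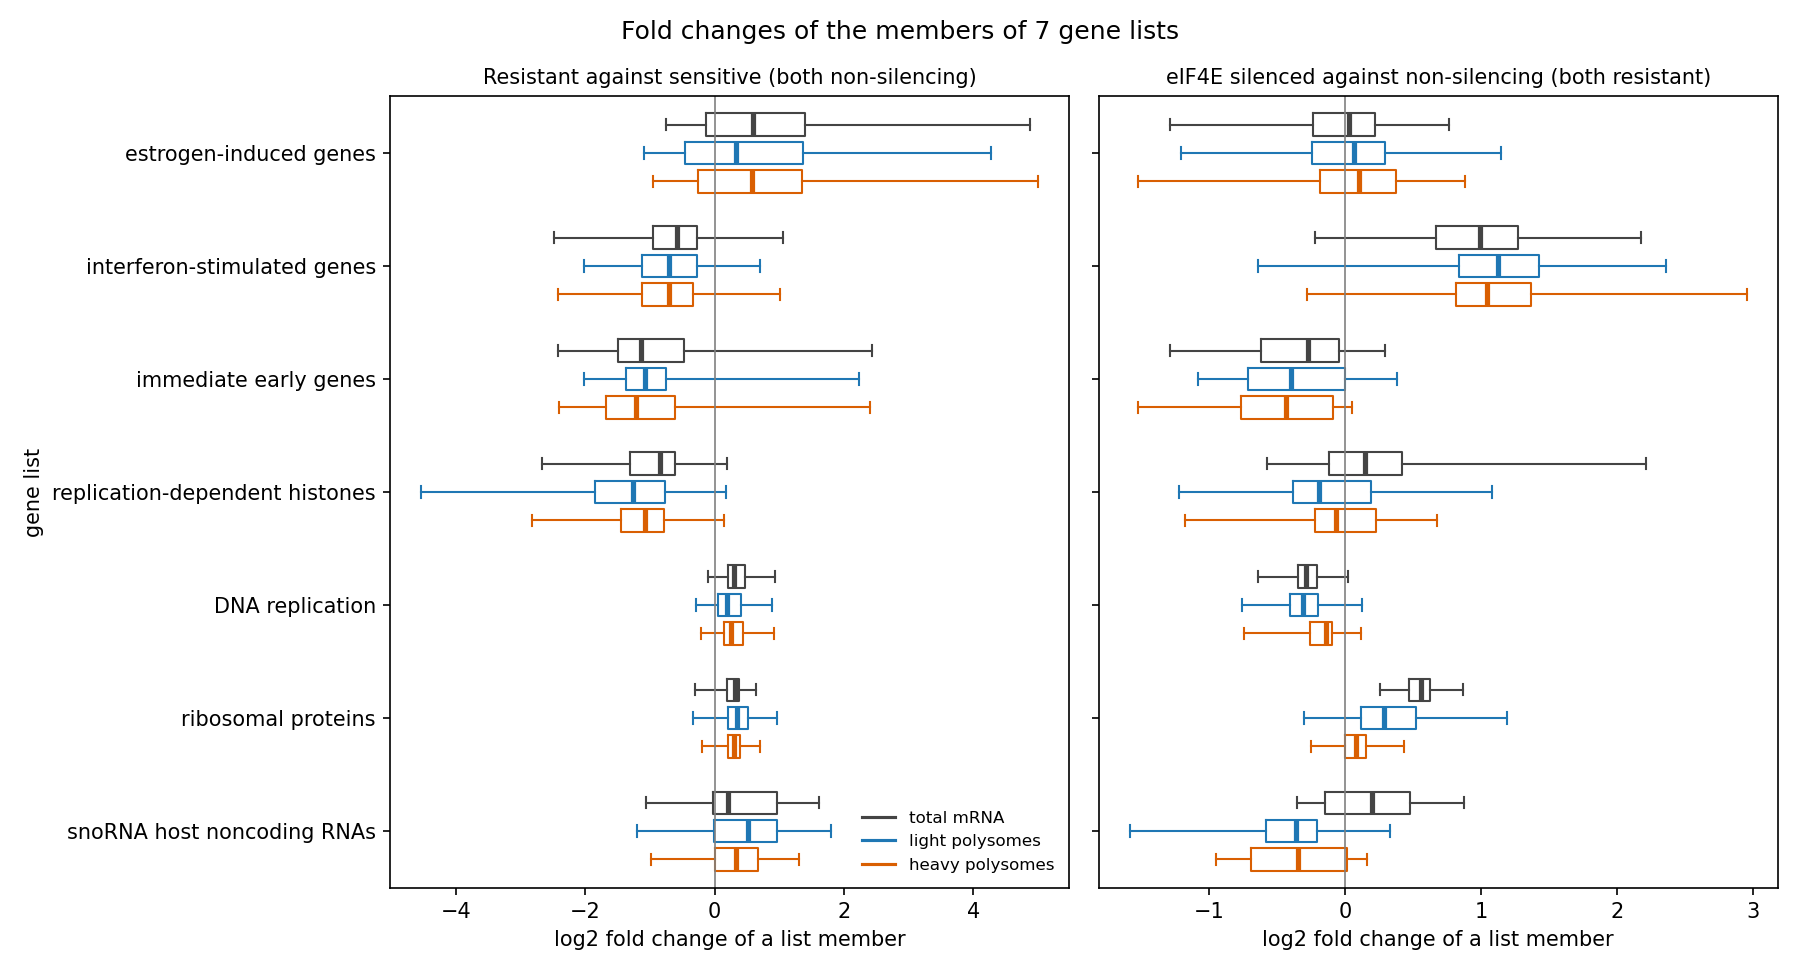
Log2 fold change of the members of 7 gene lists (horizontal axis) in total, light and heavy mRNA, for resistant against sensitive cells (left) and silenced against resistant cells (right); boxes span the quartiles, lines are medians and whiskers reach the lowest and highest member. Interferon-stimulated genes have medians of -0.57, -0.70 and -0.70 on the left and 0.99, 1.12 and 1.04 on the right.

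Whether resistance changes ribosome loading beyond the mRNA level was tested as an interaction. EIF4E had a log2 difference of 0.39 (SE 0.30, adjusted p = 1) between its heavy and total folds. The smallest p belonged to PPP3CB, a calcineurin subunit (0.68, SE 0.19), GDAP2 (0.71), the ubiquitin ligase gene RNF146 (0.60), ANKRD13C (0.61) and the lipid kinase gene PI4K2B (0.68), and none of them passed. No gene passed in edgeR, DESeq2, limma-voom or the culture block, with 232 genes at an unadjusted p under 0.05 in edgeR and 1342 in the culture block. No list was called, and ribosomal proteins had a median of 0.01 (adjusted p = 0.951). For heavy against light polysomes the smallest p belonged to HNRNPK, an RNA-binding protein gene (1.49, SE 0.26), the tubulin gene TUBB (1.64, SE 0.29), ATXN10 (1.11), the chromatin subunit gene RBBP4 (1.06) and SNX17 (1.26), each with adjusted p = 0.241. No gene passed in edgeR (701 at an unadjusted p under 0.05) or limma-voom, against 68 in DESeq2 and 322 in the culture block.

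In the list tests of heavy against light polysomes, 4 lists differed between resistant and sensitive cells. Proteasome subunits had a median of 0.18 (adjusted p = 1.21e-06), and cholesterol synthesis had 0.29 (adjusted p = 0.0110), each with adjusted p = 0.712 with an estimated correlation. Hypoxia and glycolysis had 0.06 with a mean of 0.23 (adjusted p = 0.0110) and nuclear long noncoding RNAs had -0.28 (adjusted p = 0.0110), each with adjusted p = 0.632 with an estimated correlation. No member passed, and 3 hypoxia and glycolysis members rose adjusted over the list alone. Adjusted p was 0.193, 0.159 and 0.0649 for cholesterol synthesis, hypoxia and noncoding RNAs without sensitive culture 1, and 0.202, 0.0639 and 0.0639 for cholesterol synthesis, hypoxia and the proteasome without resistant culture 2.

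Silenced against resistant cells asks what differs with the silencing of EIF4E in resistant cells. In total mRNA OAS2, an antiviral enzyme induced by interferon, rose by 1.69 (SE 0.23, adjusted p = 0.0328), from 109 ± 9.33 to 354 ± 90.6 CPM. In heavy polysomes OAS2 rose by 1.82 (SE 0.23, adjusted p = 0.0150), from 123 ± 4.70 to 437 ± 141 CPM, and the sensitive cells held 376 and 399 CPM. The other call of both was MIR30A, a microRNA gene chosen after its values were seen, with 943 counts over the 6 silenced libraries and 1 count over the 12 others. MYC had -1.29 (SE 0.51, adjusted p = 0.993) in total mRNA and -1.52 (SE 0.51, adjusted p = 0.470) in heavy polysomes, RUNX2 had -0.64 (SE 0.51, adjusted p = 0.832) in heavy polysomes, and CCND1 had -0.34 and -0.19, and none of these passed. In both kinds of library 2 genes rose and 0 fell. DESeq2 gave 28 up and 9 down in total mRNA and 54 up and 49 down in heavy polysomes, and limma-voom gave 0 falls in both. With the replicate number as a block, whose pairing of silenced with resistant cultures stays open, heavy polysomes had 19 up and 8 down. At an unadjusted p under 0.05 edgeR had 784 and 1220 genes. The OAS2 call was lost in total mRNA without resistant library 1 (1.78, 0.309) or 2 (1.61, 0.815) or silenced library 2 (1.41, 0.553), in a range of 1.84e-08 to 0.861. In heavy polysomes it was lost without the same libraries (1.86, 0.452; 1.78, 0.174; 1.41, 0.242), in a range of 3.26e-10 to 0.783.

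Interferon-stimulated genes were higher in silenced cells as a group: 44 of 45 members were positive in each kind of library. In total mRNA 1 rose (37 adjusted over the list alone) with a median of 0.99 (adjusted p = 4.24e-71, and adjusted p = 0.0138 with an estimated correlation). In heavy polysomes 1 rose (43 alone) with a median of 1.04 (adjusted p = 3.90e-64, and adjusted p = 0.0366 with an estimated correlation). IFITM1, which blocks viral entry, had 1.05 (SE 0.17) in total mRNA and 0.96 (SE 0.17) in heavy polysomes, and neither passed over all genes. DNA replication was lower in total mRNA, with a median of -0.29 (0 of 44 members passing, 2 down alone; adjusted p = 2.64e-19, and adjusted p = 0.0125 with an estimated correlation). The replication initiation factor gene MCM10 had -0.58 and the S-phase cyclin gene CCNE2 -0.50. Its median was -0.14 in heavy polysomes (adjusted p = 4.65e-06, and adjusted p = 0.154 with an estimated correlation). These list calls held without any culture. Mitosis was lower in both, at -0.21 in total mRNA (adjusted p = 2.22e-11, and adjusted p = 0.0985 with an estimated correlation) and -0.21 in heavy polysomes (adjusted p = 3.94e-06, and adjusted p = 0.282 with an estimated correlation), and its heavy call was lost without silenced culture 1 (0.0760).

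Ribosomal protein mRNAs were higher in total mRNA of silenced cells, where all 77 were positive with a median of 0.55 (0 passing; adjusted p = 1.51e-35, and adjusted p = 0.303 with an estimated correlation). RPL12 of the large subunit had 0.87 (SE 0.29). In heavy polysomes their median was 0.08 (adjusted p = 0.569), and it ranged from -0.145 to 0.223 with a silenced or resistant culture left out. Other TOP mRNAs had a median of 0.35 in total (adjusted p = 2.75e-12, and adjusted p = 0.121 with an estimated correlation) and 0.17 in heavy mRNA (adjusted p = 0.0147, and adjusted p = 0.638 with an estimated correlation). The heavy call of other TOP mRNAs was lost without resistant culture 1 (0.0865) or silenced culture 1 (0.107). Oxidative phosphorylation had 0.22 in total (adjusted p = 7e-08, and adjusted p = 0.553 with an estimated correlation) and 0.21 in heavy mRNA (adjusted p = 0.000265, and adjusted p = 0.638 with an estimated correlation), the latter lost without silenced culture 1 (0.497). Classic eIF4E-sensitive mRNAs were lower, at -0.13 in total (adjusted p = 0.0215, and adjusted p = 0.110 with an estimated correlation) and -0.12 in heavy mRNA (adjusted p = 0.00470, and adjusted p = 0.101 with an estimated correlation). No member passed, and BIRC5, an inhibitor of apoptosis, had -0.45 in heavy polysomes. The total call of this list was lost without resistant culture 1 (0.0784) or silenced culture 1 (0.0788), and the heavy call without silenced culture 1 (0.0768). In total mRNA the stress response list was called up (median 0.16, adjusted p = 0.00289) and immediate early genes down (-0.27, 0.000653), each with adjusted p = 0.553 with an estimated correlation, and cholesterol synthesis down (-0.12, 0.0489, and adjusted p = 0.685 with an estimated correlation). The stress response call was lost without silenced culture 2 (0.794), the immediate early one without resistant culture 1 (0.263) and the cholesterol one without resistant culture 1 (0.131) or silenced culture 1 (0.257).

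Further lists were called in heavy polysomes of silenced cells with no member passing. The stress response list had a median of 0.28 (adjusted p = 0.000144) and immediate early genes had -0.44 (1 down alone; adjusted p = 4.96e-06), each with adjusted p = 0.385 with an estimated correlation. Aminoacyl-tRNA synthetases had 0.19 (adjusted p = 0.000299, and adjusted p = 0.333 with an estimated correlation), snoRNA hosts -0.35 (adjusted p = 0.000378, and adjusted p = 0.507 with an estimated correlation) and growth factor receptors 0.29 (adjusted p = 0.0116, and adjusted p = 0.464 with an estimated correlation). Proteasome subunits had 0.22 (adjusted p = 0.000533) and NRF2 targets 0.20 (adjusted p = 0.0131), each with adjusted p = 0.638 with an estimated correlation. Without silenced culture 2 adjusted p was 0.331 for the stress response, 0.261 for synthetases, 0.256 for the proteasome, 0.261 for NRF2 targets, 0.475 for receptors and 0.311 for snoRNA hosts. Without resistant culture 1 it was 0.516 for immediate early genes (median 0.03), 0.0813 for snoRNA hosts and 0.216 for receptors, and without resistant culture 2 it was 0.174 for NRF2 targets. Uncalled in heavy polysomes, by median and adjusted p, were estrogen-induced genes (0.10, 0.948), luminal genes (0.13, 0.122), basal and mesenchymal genes (0.27, 0.566), RUNX2 targets (-0.16, 0.990), hypoxia and glycolysis (0.15, 0.0824), p53 targets (-0.01, 0.948), histones (-0.07, 0.630), cholesterol synthesis (0.03, 0.881) and eIF4F subunits (-0.00, 0.882). Signs of median, mean and test differed for the mTOR pathway (0.01, -0.00, down, 0.990), NF-kB genes (0.01, -0.19, down, 0.625), apoptosis regulators (0.03, 0.04, down, 0.778), nuclear noncoding RNAs (0.06, 0.02, down, 0.990) and leukocyte markers (-0.08, 0.08, down, 0.948).

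In light polysomes silencing raised 33 genes and lowered 2, and with the replicate number as a block, a pairing that stays open, 194 rose and 61 fell. IFI44L, an interferon-induced gene, rose by 2.26 (SE 0.30, adjusted p = 0.0148), from 31.7 ± 5.27 to 152 ± 41.5 CPM, the netrin receptor gene UNC5C by 2.66 (SE 0.39, adjusted p = 0.0207) and OAS2 by 1.73 (SE 0.23, adjusted p = 0.0148). The glycolytic enzyme gene GAPDH rose by 1.14 (SE 0.18, adjusted p = 0.0274), and the falls were EIF4E and ZC3H12A, an RNase that limits inflammation (-1.33, SE 0.22, adjusted p = 0.0292). IFI44L, UNC5C and ZC3H12A were chosen after their values were seen. Interferon-stimulated genes had 6 of 45 up (38 alone; median 1.12, adjusted p = 1.09e-49) and DNA replication 0 passing (5 down alone; median -0.31, adjusted p = 1.95e-12), each with adjusted p = 0.0445 with an estimated correlation. Other TOP mRNAs had 4 of 27 up (10 alone; median 0.46, adjusted p = 4.15e-15, and adjusted p = 0.0880 with an estimated correlation). The ribosomal protein median of 0.28 (adjusted p = 1.13e-07, and adjusted p = 0.755 with an estimated correlation) became -0.07 without silenced culture 1 (adjusted p = 0.342). The 35 calls were 0 without resistant light library 1 or 2 or silenced light library 2, and 9 without silenced light library 1, so no gene call of this paragraph holds without each of the former 3.

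Whether silencing changes ribosome loading beyond the mRNA level was asked by the same interaction. Ribosomal protein mRNAs were lower in heavy against total mRNA after silencing, with a median of -0.47 and 0 of 77 members positive (camera adjusted p = 1.33e-38, and adjusted p = 0.387 with an estimated correlation). In the culture block the list gave adjusted p = 1.34e-68, with 49 members down adjusted over the list alone and 0 over all genes, and adjusted p = 0.178 with an estimated correlation. The snoRNA host noncoding RNAs, whose introns encode small nucleolar RNAs, had a median of -0.56 with 0 of 18 positive (adjusted p = 1.31e-11, and adjusted p = 0.387 with an estimated correlation). Other TOP mRNAs had -0.17 (adjusted p = 1.26e-05, and adjusted p = 0.465 with an estimated correlation). The smallest p of single genes belonged to DPY19L2P2 (-0.83), the ribosomal stalk protein gene RPLP0 (-0.61), MMP24 (-0.57), the poly(A)-binding protein gene PABPC1 (-0.69) and ATMIN (-0.60), and none passed. No gene passed in edgeR (91 at an unadjusted p under 0.05), DESeq2, limma-voom or the culture block (655), and the culture block called 21, all down, without silenced culture 1.

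**Figure D3:**
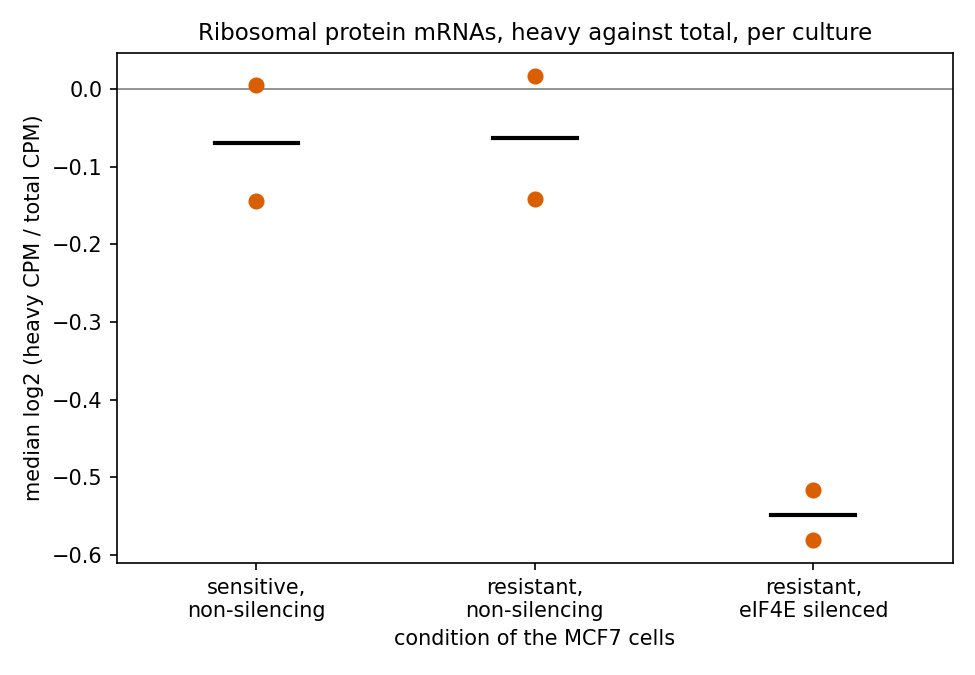
Median over ribosomal protein genes of log2 heavy CPM over total CPM (vertical axis) in each culture (points) of sensitive, resistant and silenced cells, with bars at the mean of 2 cultures. The silenced cultures sit at -0.516 and -0.581 and the resistant ones at 0.0167 and -0.142.

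Of the other lists, proteasome subunits had 0.15 (adjusted p = 3.99e-05) and histones -0.21 (adjusted p = 0.0134), each with adjusted p = 0.660 with an estimated correlation. DNA replication had 0.12 (adjusted p = 0.000227) and hypoxia and glycolysis 0.15 (adjusted p = 0.0134), each with adjusted p = 0.387 with an estimated correlation. Cholesterol synthesis had 0.14 (adjusted p = 0.00420) and nuclear noncoding RNAs -0.22 (adjusted p = 0.0309), each with adjusted p = 0.501 with an estimated correlation. Aminoacyl-tRNA synthetases had 0.13 (adjusted p = 0.00369, and adjusted p = 0.465 with an estimated correlation) and growth factor receptors 0.17 (adjusted p = 0.0384, and adjusted p = 0.623 with an estimated correlation). Each of these 8 calls was lost without silenced culture 2, at adjusted p = 0.116 for the proteasome, 0.760 for histones, 0.0923 for DNA replication, 0.165 for hypoxia, noncoding RNAs and receptors, 0.418 for cholesterol synthesis and 0.236 for synthetases, whereas ribosomal proteins, other TOP mRNAs and snoRNA hosts kept theirs without any culture. Without resistant culture 1 adjusted p was 0.132 for hypoxia, 0.375 for noncoding RNAs, 0.420 for receptors, 0.0734 for cholesterol synthesis, 0.237 for synthetases and 0.443 for histones, and without silenced culture 1 it was 0.0518 for receptors. Classic eIF4E-sensitive mRNAs had a median of 0.00 with a mean of -0.05 (adjusted p = 0.436).

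For heavy against light polysomes after silencing, other TOP mRNAs had a median of -0.33 (adjusted p = 5.12e-09), ribosomal proteins -0.27 (adjusted p = 2.69e-06), proteasome subunits 0.16 (adjusted p = 6.34e-05) and DNA replication 0.10 (adjusted p = 0.00795), all with adjusted p = 0.989 with an estimated correlation. The smallest p of single genes belonged to NUBP1, an iron-sulfur assembly factor (1.39), the RNA methyltransferase gene FTSJ1 (1.18), the deubiquitinase gene OTUB1 (1.24), COPE of the vesicle coat (1.35) and MRPS35 (1.04), with adjusted p = 1. No gene passed in edgeR (408 at an unadjusted p under 0.05), DESeq2 or limma-voom, and 20 passed in the culture block. Without silenced culture 1 these lists were not called, at adjusted p = 0.172, 0.379, 0.0518 and 0.172. The proteasome was also lost without resistant culture 1 (0.517) and DNA replication without resistant culture 2 (0.174).

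Silenced resistant cells against sensitive cells in heavy polysomes asks how far silenced cells differ from the sensitive state. PI15 stayed 8.28 higher (SE 0.37, adjusted p = 7.07e-08), GNAI1 7.96 higher and GPC6, a cell surface proteoglycan gene, 6.61 higher, while FAM109B was lower at -7.09 and EPDR1, with 0 counts against 614, at least 170-fold lower; these genes were chosen after their values were seen. RUNX2 was 3.00 higher (SE 0.60, adjusted p = 0.00411; 0.0587 without silenced culture 1, in a range of 6.82e-06 to 0.0587) and EIF4E did not pass (0.27, SE 0.22, adjusted p = 0.409). MYC was lower at -1.98 (SE 0.52, adjusted p = 0.0170), a call lost without silenced heavy library 1 (-2.02, 0.0833) or 2 (-2.06, 0.0901) or sensitive heavy library 2 (-1.15, 0.169), in a range of 0.000230 to 0.169. There were 1636 rises and 1431 falls, 3067 in all, and fewer calls without any of the silenced or sensitive heavy libraries. Rises made up 53.3% of the calls, but 46.3% of 2553 without the low-count filter. In a model of the contrast's own libraries they made up 39.9% of 949. Rises outnumbered falls in the other planned fits of all libraries. Of the 2098 genes called for resistance in heavy polysomes, 1658 were called in the same direction here, against 112 up and 91.9 down for independent lists, and the median ratio of the folds was 0.982. Both contrasts use the same 2 sensitive heavy libraries, and 20 simulations of that sharing alone gave 0 shared calls and a median ratio of 0.496 (0.469 to 0.521) over as many genes of smallest p. The folds correlated at 0.883 with a covariance of 0.756, beside 0.484 and 0.0884 in the simulations, and part of this may come from the shared libraries. These simulations held no real change, so calls, and with them shared calls, could hardly arise. Real changes also alter the ratio and the correlation. The simulated calls, ratio and correlation therefore do not measure how much of the overlap comes from sharing.

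By list, 21 of 26 immediate early genes were lower in silenced than in sensitive cells (21 down and 1 up alone; median -1.62, adjusted p = 1.25e-15, and adjusted p = 0.136 with an estimated correlation), such as IER3 (-2.47, SE 0.19) and ZFP36 (-2.35). Estrogen-induced genes had 13 of 44 up and 2 down (17 and 3 alone; median 0.70, adjusted p = 5.16e-06, and adjusted p = 0.0560 with an estimated correlation), such as PRSS23 (5.30). Interferon-stimulated genes had 7 of 45 up and 1 down (7 and 1 alone; median 0.32, adjusted p = 0.0679) and were not called. Proteasome subunits had 11 of 31 up (20 alone; median 0.47, adjusted p = 4.01e-06, and adjusted p = 0.839 with an estimated correlation), among them PSMB7 (0.71; 0.61 and adjusted p = 0.0814 without silenced culture 2, in a range of 4.52e-05 to 0.0814). Oxidative phosphorylation had 18 of 74 up (22 alone; median 0.34, adjusted p = 1.28e-05, and adjusted p = 0.877 with an estimated correlation), with the succinate dehydrogenase subunit SDHB at 0.97. Aminoacyl-tRNA synthetases had 9 of 20 up (13 alone; median 0.47, adjusted p = 0.000391, and adjusted p = 0.606 with an estimated correlation), and other TOP mRNAs 7 of 27 (9 alone; median 0.43, adjusted p = 0.000278, and adjusted p = 0.741 with an estimated correlation). NF-kB genes (7 of 18 down, 1 up; 7 and 2 alone; median -0.30, adjusted p = 0.00171) and histones (7 of 22 down; 8 alone; median -1.10, adjusted p = 4.01e-06) were lower, each with adjusted p = 0.646 with an estimated correlation. The ribosomal protein median of 0.37 (6 up; 1 alone; adjusted p = 0.00102, and adjusted p = 0.877 with an estimated correlation) lost its call without silenced culture 1 (0.274) or sensitive culture 2 (0.561). Without silenced culture 1 or 2 the members called were 7 and 6 for immediate early genes, 3 and 2 for the proteasome, 6 and 4 for oxidative phosphorylation, 5 and 0 for synthetases, 4 and 3 for other TOP mRNAs, 2 and 3 for NF-kB genes, 4 and 1 for histones and 1 and 4 for ribosomal proteins. Oxidative phosphorylation had 30 and ribosomal proteins 12 without sensitive culture 1, and without sensitive culture 2 they had 10 and 0, the proteasome, synthetases and other TOP mRNAs 4 each and histones 12.

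Genes moved in opposite directions by resistance and by silencing would be those that silencing returns toward the sensitive level. In heavy polysomes 1 gene, OAS2, was called in opposite directions, lower in resistant than in sensitive cells and higher after silencing, against 0.128 expected for independent calls, and 0 genes were called in the same direction. Across all genes the 2 sets of folds correlated at -0.117 and 52.5% had opposite signs. The resistant heavy libraries enter both contrasts, and 20 simulations of that sharing alone gave a mean correlation of -0.503 (-0.529 to -0.486), opposite signs in 66.8% of genes and 0 opposite calls. The covariance of -0.0472 compared with -0.0930 in the simulations, a difference of 0.0458. The simulations held no real change, whereas resistance had 2098 calls in heavy polysomes. Real changes in a contrast weaken the correlation and the share of opposite signs, so these cannot be set against the simulated ones. Without real changes calls hardly arise, so the 0 opposite calls of the simulations are no measure either. The covariance was less negative than in any simulation (-0.102 to -0.0883). It is a net over all genes, so genes that moved the same way can hide others that moved oppositely. The simulations also gave all heavy groups the same spread, on which the simulated covariance depends. This comparison therefore cannot decide whether genes moved oppositely beyond sharing. The SD of the log2 difference between heavy replicates was 0.525 in resistant, 0.499 in silenced and 0.681 in sensitive cells. With 2 resistant heavy libraries, the contrasts were not tested on separate controls, and part of the opposite call may come from the shared ones. The OAS2 call rests on the libraries named above: without resistant heavy library 1 or 2 or silenced heavy library 2 the count was 0.

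Heavy against light polysomes, averaged over the 3 conditions, asks which mRNAs carry more ribosomes. CLU, a secreted chaperone gene, was higher in heavy polysomes by 2.66 (SE 0.23, adjusted p = 3.42e-07), the keratin gene KRT8 by 2.35, the chaperone gene CALR by 2.30 and the serine synthesis enzyme gene PHGDH by 2.29. The noncoding RNAs NEAT1 (-2.48), OIP5-AS1 (-2.46) and SNHG6 (-2.45) and the short mRNA COMMD6 (-2.35) were lower. EIF4E itself was lower in heavy polysomes (-1.71, SE 0.13, adjusted p = 1.13e-07), as were EIF4EBP1 (-0.60) and MKNK1 (-0.41), and CCND1 (0.81) and MTOR (0.75) were higher. Of 15845 genes 4831 were higher and 5082 lower. Synthetases (20 of 20 up; 20 alone; median 1.05, adjusted p = 3.78e-14, and adjusted p = 0.0296 with an estimated correlation), hypoxia and glycolysis (23 of 31 up, 4 down; 24 and 4 alone; median 0.91, adjusted p = 1.05e-09, and adjusted p = 0.0128 with an estimated correlation) and DNA replication (29 of 44 up, 3 down; 30 and 3 alone; median 0.57, adjusted p = 1.05e-09, and adjusted p = 0.0400 with an estimated correlation) were heavy. Ribosomal proteins had 49 of 77 members down and 8 up (49 and 8 alone; median -0.65, adjusted p = 1.61e-05, and adjusted p = 0.727 with an estimated correlation). The snoRNA hosts had 17 of 18 down (17 alone; median -1.37, adjusted p = 9.54e-07, and adjusted p = 0.246 with an estimated correlation).

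Heavy polysomes against total mRNA, averaged the same way, asks which transcripts are well loaded relative to their abundance. The lipoprotein gene APOE was higher by 0.88 (SE 0.14, adjusted p = 0.000760), with PCSK1N and the ribosome assembly gene WDR18 at 0.83 and MACROD1 at 0.81. The noncoding RNAs BCYRN1 (-2.50), NEAT1 (-2.21), SNHG3 (-1.94) and SNHG5 (-1.85) were lower, and EIF4E was lower too (-0.89, SE 0.12, adjusted p = 0.000425). There were 2206 higher and 2152 lower genes. Proteasome subunits had 24 of 31 up (26 alone; median 0.48, adjusted p = 1.86e-15, and adjusted p = 0.218 with an estimated correlation), while snoRNA hosts had 15 of 18 down (16 alone; median -1.08, adjusted p = 1.86e-15, and adjusted p = 0.0755 with an estimated correlation). Ribosomal proteins had 24 of 77 down and 2 up (25 and 2 alone; median -0.25, adjusted p = 7.66e-05, and adjusted p = 0.769 with an estimated correlation). The 4358 calls were 2038 without resistant culture 1, 2194 without resistant culture 2, 2688 without silenced culture 1 and 2484 without silenced culture 2, and the culture block called 4423 higher and 3963 lower.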

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

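Of the tests in this part, the one on MIR30A, every value of the culture block and every value with a whole culture left out were chosen only after the result was seen. The lists and genes of the last 2 paragraphs, and the ribosomal proteins, were picked out by a test of a difference between groups, an interaction of condition with polysome fraction.

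Estrogen-induced genes were higher in resistant than in sensitive cells (list median 0.58 in heavy polysomes) while their receptor gene ESR1 was lower. A single sensitive culture with low estrogen-induced genes is argued against as the cause: against sensitive culture 1, the higher one, the resistant cultures still had list medians of at least 0.454, and the 4 pairs of cultures gave 0.454, 0.573, 0.618 and 0.889. What stays open is a biological difference of the resistant line, which may include its growth in 4-hydroxytamoxifen, a partial agonist of the receptor, and which these samples did not test apart from selection.

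Interferon-stimulated genes were higher in silenced than in resistant cells (list median 1.04 in heavy polysomes), and this did not come from a single silenced culture: the lowest of the 4 pairs of cultures was 0.619 and the others were 1.03, 1.18 and 1.52. Silenced minus sensitive cultures gave 0.0582, 0.0786, 0.610 and 0.555, and resistant minus sensitive cultures -0.592, -0.698, -0.760 and -0.862. MIR30A had 943 counts over the 6 silenced libraries and 1 over the 12 others, and since hairpin vectors may carry the backbone of this microRNA, a response to the vector and a response to the loss of eIF4E cannot be told apart: every silenced library has both.

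Ribosomal protein mRNAs were lower in heavy against total mRNA after silencing (list median -0.469), while their total mRNA was higher (0.553). Random sets of other genes were matched on coding length (median 516 against 468), expression and the heavy against total ratio in resistant cells. Short mRNAs matched in this way do not give the pattern. The lowest median of these sets was -0.207 for heavy against total, and in total mRNA the highest was 0.211. The matched genes were still less abundant (median log2 CPM 8.73 against 9.82), so that abundance stays open. Both silenced cultures were low, with a gap of 0.375 between the lowest resistant and the highest silenced culture. Both calls were lost with an estimated correlation (adjusted p = 0.387 for heavy against total and 0.303 for total mRNA). What stays open is a response to the silencing or its vector, by a mechanism that was not tested here, and other TOP mRNAs had a median of only -0.17.

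For the change in translational efficiency after silencing, ribosomal proteins had a median of -0.47, other TOP mRNAs -0.17, snoRNA hosts -0.56, nuclear long noncoding RNAs -0.22 and histones -0.21. Growth factor receptors had 0.17, cholesterol synthesis 0.14, DNA replication 0.12, aminoacyl-tRNA synthetases 0.13, hypoxia and glycolysis 0.15 and proteasome subunits 0.15. With an estimated correlation all 11 calls were lost (adjusted p = 0.387 to 0.660), and without silenced culture 2 all but those of ribosomal proteins, other TOP mRNAs and snoRNA hosts were lost (0.0923 for DNA replication to 0.760 for histones). For heavy against light polysomes after silencing, ribosomal proteins had -0.27, other TOP mRNAs -0.33, DNA replication 0.10 and proteasome subunits 0.16, all lost with an estimated correlation (adjusted p = 0.989) and without silenced culture 1 (0.379, 0.172, 0.172 and 0.0518). For heavy against light polysomes in resistance, cholesterol synthesis had 0.29, hypoxia and glycolysis 0.0646, proteasome subunits 0.18 and nuclear long noncoding RNAs -0.28. All 4 were lost with an estimated correlation (adjusted p = 0.632 to 0.712), noncoding RNAs also without sensitive culture 1 (0.0649), the proteasome without resistant culture 2 (0.0639), and cholesterol synthesis and hypoxia without either (0.193 and 0.202, 0.159 and 0.0639).

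With the culture block, 322 genes differed in heavy against light polysomes between resistant and sensitive cells, 305 up and 17 down. TUBB, a tubulin gene, had 1.65 (adjusted p = 0.000666), HNRNPK, an RNA-binding protein gene, 1.51 (0.000420), the splicing factor gene PRPF19 1.44 (0.000666) and SNX17 1.27 (0.00221). ATRNL1 had -1.41 (0.00363), PEX6 -1.17 (0.00363), the RNA demethylase gene FTO -0.95 (0.00484) and ANO9 -0.90 (0.0147). After silencing 20 genes differed, 12 up and 8 down: NUBP1 had 1.39 (0.0112), the quinone reductase gene NQO1 1.34 (0.0126), OTUB1 1.24 (0.0431) and FTSJ1 1.15 (0.0431), and FAM59B had -1.10 (0.0466), TMEM219 -0.99 (0.0126), RPL3 -0.96 (0.0431) and TLE2 -0.96 (0.0431). With a culture left out the resistance count was 333, 10, 0 and 63 without resistant culture 1, sensitive culture 1, resistant culture 2 and sensitive culture 2, and the silencing count was 0, 166, 104 and 214 without resistant culture 1, silenced culture 1, resistant culture 2 and silenced culture 2.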

How the results depend on the processing

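Depth was not the main limit, since counting error was small beside the spread between 2 replicates per group. In the tests of single genes and settings 26990 kept their side of the threshold, 312 came to pass and 1656 no longer passed. Of the 26990, 9660 passed in both fits, all with the same sign, and among those that passed in neither 448 changed sign. In the list tests 2497 kept their side, 224 of them uncalled with a median of the other sign, 77 came to pass, 249 no longer passed and 5 were reversed, and of the counts 194 stayed within 1.5 times their value and 89 did not. The culture block and every setting that leaves out a whole culture were chosen only after the result was seen.

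Without the low-count filter silencing in heavy mRNA called 4 genes, and 2 genes moved in opposite directions with resistance and silencing. DESeq2 called 68 genes for resistance in heavy against light mRNA, and for silencing 37 in total, 103 in heavy and 314 in light mRNA, with 31 in opposite directions. The replicate number as a block pairs cultures of the same number across conditions, a link that stays open. With it resistance had 2591, 3398 and 3613 calls in total, heavy and light mRNA, and silencing 27 in heavy and 255 in light mRNA. Silenced against sensitive cells in heavy mRNA had 4336, and 9 genes moved in opposite directions with resistance and silencing. In a model of the contrast's own libraries, with fewer degrees of freedom, resistance had 401, 571 and 989 calls, silencing 1 in heavy and 6 in light mRNA, silenced against sensitive cells 949, and 0 genes moved in opposite directions. For the settings of this paragraph the cause was not tested.

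With the culture block, 322 genes passed for resistance and 20 for silencing in heavy against light mRNA, and 8386 for heavy against total mRNA. With a culture left out as well, the resistance count was 333, 10, 0 and 63 without resistant culture 1, sensitive culture 1, resistant culture 2 and sensitive culture 2. For silencing it was 0, 166, 104 and 214 without resistant culture 1, silenced culture 1, resistant culture 2 and silenced culture 2. Translational efficiency after silencing had 21 calls, all down, without silenced culture 1. Heavy against total mRNA had 7282, 8047, 6973, 7322, 7793 and 7171 calls without resistant 1, silenced 1, sensitive 1, resistant 2, silenced 2 and sensitive 2. The cause was not tested.

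With an estimated correlation 10 list tests passed, so most list calls at the preset correlation of 0.01 depend on that setting. With fry, a test of each list on its own rather than against other genes, 70 passed. With 1 library or 1 culture left out, where the lone library is assumed to vary like those of other groups, calls ranged from 426 to 1951 (resistance, total), 616 to 2154 (heavy), 748 to 2539 (light), 0 to 2 (silencing, total), 0 to 6 (heavy) and 0 to 11 (light). They ranged from 881 to 3186 for silenced against sensitive cells, 2038 to 4330 for heavy against total mRNA and 0 to 2 for opposite directions. List medians that reversed ranged from -0.365 to 0.451 for histones (resistance, heavy against light), -0.145 to 0.223 and -0.0671 to 0.611 for ribosomal proteins (silencing, heavy and light mRNA), -0.811 to -0.0783 for snoRNA hosts (silencing, light mRNA, where the test's direction turned) and -0.509 to -0.0365 for histones (silencing, heavy against total, likewise).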

Other observations

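Of the tests of this part, the splits that part every pair were chosen only after the result was seen, since the pairing was read from the data, and the windows along the chromosomes were not in the prediction written before.

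Other lists parted heavy from light polysomes in the mean of the 3 conditions. Proteasome subunits had 27 of 31 members up and 1 down (28 and 1 adjusted over the list alone; median 0.98, adjusted p = 3.78e-14, and adjusted p = 0.239 with an estimated correlation). Cholesterol synthesis had 20 of 25 up and 1 down (20 and 1 alone; median 0.76, adjusted p = 7.59e-06, and adjusted p = 0.192 with an estimated correlation). Mitosis had 31 of 40 up and 5 down (32 and 5 alone; median 0.62, adjusted p = 1.68e-05, and adjusted p = 0.246 with an estimated correlation). Histones had 20 of 22 down (20 alone; median -1.39, adjusted p = 2.27e-06, and adjusted p = 0.312 with an estimated correlation), nuclear long noncoding RNAs 11 of 13 down (11 alone; median -1.03, adjusted p = 0.000114, and adjusted p = 0.192 with an estimated correlation) and apoptosis regulators 16 of 26 down and 4 up (16 and 4 alone; median -0.42, adjusted p = 0.0146, and adjusted p = 0.192 with an estimated correlation).

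The fraction counts were compared with other splits of the same 12 libraries, with condition as a term. For heavy against total mRNA the real split called 4932 genes and the highest of the other drawn splits 127, so that 1 of 40 splits called as many. For heavy against light polysomes the real split called 9895 genes, the highest of the others 1, and 1 of 40 splits called as many. The real split parts all 6 pairs of libraries from a culture, while the highest other drawn split parted 0. Among the 32 splits that part every pair, real one included, the highest other called 0 genes in both comparisons. The real split is itself counted, so 1 of 40 and 1 of 32 are the smallest shares that could arise. No other split that was run called as many genes.

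A hypothesis on resistance was that gains or losses of chromosome segments differ between the cultures, so that neighbouring genes change together. Among 15107 genes placed on chromosomes, the total mRNA folds of adjacent genes correlated at a Spearman rho of 0.209, against at most 0.0230 in 100 shuffles of gene order and 0.0718 for the folds of silencing. For genes 10 and 50 apart it was 0.0869 and 0.0547. Of 568 overlapping windows of 50 genes, 43 had a median beyond 0.32, the maximum of shuffled blocks that did not overlap. The extremes ran from SMG9 to FOSB (-0.67, 34% of genes positive), from HIST1H2AB to HIST1H2BO (-0.58, 20%) and from TRERF1 to ENPP5 (0.45, 86%). The second of these spans histone genes, a list that was lower in resistant cells and is measured incompletely here. The values are consistent with segments of changed dosage, but differences between the replicates of sensitive cells (rho 0.170) and of resistant cells (0.162) were nearly as large, so joint regulation of neighbours may account for part of it, and DNA was not analysed here.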
